A study of Mus musculus with 12 samples.

How the data were processed

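Poly-A RNA from the livers of 12 adult female mice was sequenced, 1 library per mouse, with 3 mice in each of 4 genotype groups. Per the labels the mice were C57BL/6, 6 months old, and had eaten a high-fat diet over 13 weeks. AHR Flox and ARNT Flox are control lines in which the Ahr or the Arnt gene carries recombination sites, and AHR KO and ARNT KO are the matching lines with loss of that gene in the liver. The recombinase line that deleted the genes, and the part of each gene that was removed, are not given in the sources used here.

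The deposited table holds raw counts per gene, whole numbers for 22537 gene symbols in 12 columns, 1 per library. Per the labels, RNA was extracted with Trizol, poly-A RNA was selected and libraries were made with NEBNext Ultra II. The submitters' processing notes name bcl2fastq 2.20, STAR 2.5.4b and 2.6.0c, R 3.5.1 and DESeq2 1.20.0 with the mm10 build. The counting tool, its strand setting and the annotation are not given in the sources used here. Reads were not used here, so counts could not be divided among the exons of a gene. Total counts ran from 23585909 to 33255004 per library, and 3 counts, the limit that a count of 0 allows, corresponded to 0.0902 to 0.127 CPM (counts scaled to a common library total). These limits cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group were duplicates of each other: the chi-square per degree of freedom between them ran from 17.5 to 249.

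Differential expression was computed with edgeR 4.0.16 in R 4.3.3, in 1 fit of all 12 libraries with a mean per group and no covariate. Genes were kept with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 13968 genes with 99.98% of the reads. Libraries were scaled with TMM, and the quasi-likelihood F test, which is two-sided, was adjusted over all genes tested with the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, with no minimum fold change. The common biological coefficient of variation was 17.5%. Log2 changes are given with the standard error (SE) from the fit, and CPM as mean ± SD over n = 3 libraries. Positions come from the RefSeq annotation of the mm10 genome, matched by symbol for 99.3% of tested genes.

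The contrasts, the gene lists, the rule for naming genes and all alternatives but those named as added were set before the data were examined. The contrasts were AHR KO against AHR Flox, ARNT KO against ARNT Flox, the difference between those effects, and ARNT Flox against AHR Flox, with a count of the genes called in both knockouts. Of 34 gene lists of liver pathways and cell type markers, 32 had enough tested members. The mitochondrially encoded genes had 0 of 13 members in the table, and only 2 of 20 pancreas markers were tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. Members past the threshold were also counted with p adjusted over the list alone.

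The rule for naming genes takes Ahr and Arnt; the called genes with the largest rise and fall per contrast, at a mean of at least 1 CPM and with all 3 libraries of a group on one side of the other 3; and, per list, its members with the smallest p. For the difference between effects the condition on sides was not applied, since 4 groups enter it. Genes named outside this rule, or in a contrast for which it did not name them, were chosen after their values were seen. Results for some genes are not reported here.

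The alternatives were DESeq2 size factors, upper quartile scaling, TMM without the 50 most abundant genes, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the groups of a contrast, the replicate number as a block, and leaving out each library in turn. After seeing the data, limma-voom with sample quality weights was added, and the fit without ARNT KO replicate 3 was reported beside the numbers of genes called and of lists that passed in each comparison. The labels pair no samples. The replicate numbers were checked on the residuals: libraries of the 2 Flox groups with the same number correlated at 0.327, 0.153 and 0.101, so the blocked count is given for that contrast. A new table was simulated from the mean of each gene over all libraries, the library sizes and the spread per gene. Changes were planted in genes above 1 CPM. There edgeR recovered 80% of 2-fold and 95% of 4-fold changes in the AHR contrast with 5 false calls. In the difference between effects it recovered 56% and 86% with 10 false calls. The simulation held no outlying library and no difference between the control lines, so these shares may overstate recovery in the real data.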

Results

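Liver RNA was measured in 12 adult female mice on a high-fat diet, 3 in each of the groups AHR Flox, AHR KO, ARNT Flox and ARNT KO. AHR is the aryl hydrocarbon receptor, a ligand-activated transcription factor, and ARNT is its DNA-binding partner, which also pairs with the hypoxia-inducible factors. The comparisons ask which liver transcripts differ after loss of either protein in females on this diet. Total counts were 29935034, 30949279 and 25441488 in AHR Flox, 32647216, 31031126 and 33255004 in AHR KO, 31550401, 32052905 and 23585909 in ARNT Flox, and 32832572, 31358605 and 29240123 in ARNT KO. The first principal component of log2 CPM held 43.0% of the variance and set ARNT KO replicate 3 apart, at 65.3 against −30.9 to 30.3 for the other libraries. That library differed from its group mates by 0.304 log2 units in the median gene, against 0.128 to 0.241 for the others, and its TMM factor was 1.19. The numbers of genes called and of lists that passed in each comparison are therefore also given without it, a choice made after the data were seen.

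**Figure D1:**
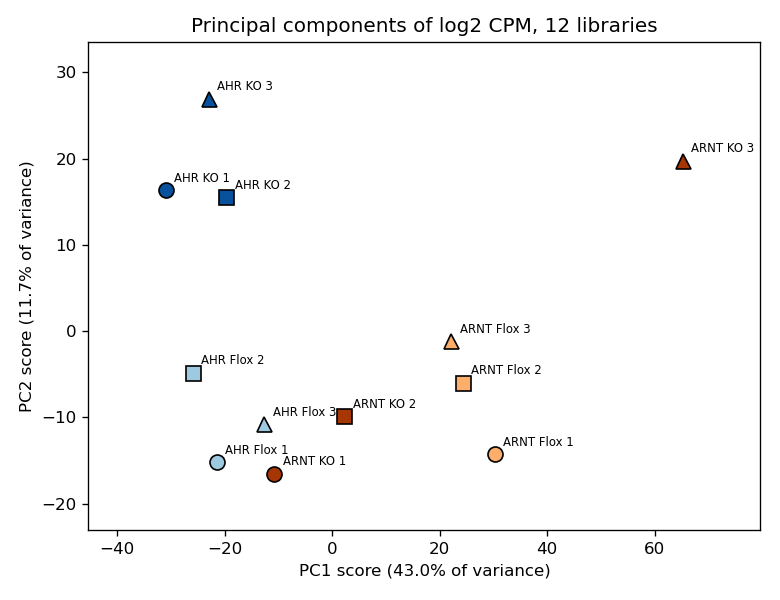
Principal components of log2 CPM, one point per library, colored by group, with the first component (43.0% of variance) on the horizontal axis and the second (11.7%) on the vertical axis. ARNT KO replicate 3 lies at 65.3 on the first component.

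The targeted genes were read in every library first. Arnt (chromosome 3, 95434367 to 95497240, mm10) fell 2.21-fold in ARNT KO, from 50.2 ± 2.33 to 22.7 ± 3.30 CPM (log2 change −1.15 ± 0.12 SE, adjusted p = 0.00601). The 3 ARNT KO libraries held 25.2, 23.9 and 19.0 CPM of Arnt, all below the ARNT Flox libraries. Leaving out ARNT Flox replicate 2 moved the adjusted p of Arnt to 0.0557, within a range of 9.86e-13 to 0.0747 over all alternatives. Ahr (chromosome 12, 35497979 to 35534989) was not lower in the libraries labelled AHR KO, at 86.5 ± 7.48 CPM against 68.4 ± 12.9 CPM in AHR Flox (log2 change 0.34 ± 0.17 SE, adjusted p = 0.470). Counts over the whole gene do not check that label, because a deletion of part of a gene can leave the rest of its transcript, and the part removed is not stated. Ahr did not pass the threshold in ARNT KO either (log2 change −0.09, adjusted p = 1.00).

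**Figure D2:**
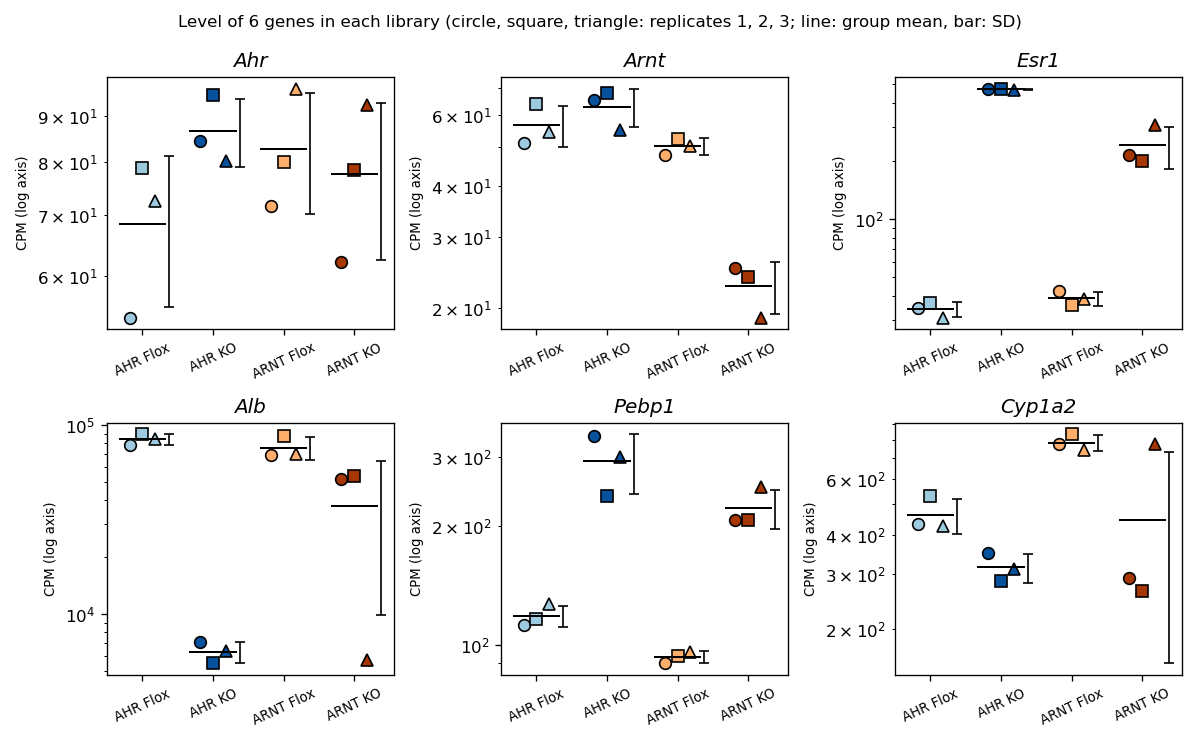
CPM of Ahr, Arnt, Esr1, Alb, Pebp1 and Cyp1a2 on a log axis, one point per library, with a line at the mean and a bar for the SD of each group of 3. Esr1 lies near 471 CPM in AHR KO and at 199 to 307 CPM in ARNT KO, and Alb is near 6311 CPM in AHR KO.

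In the libraries labelled AHR KO, transcripts assigned to Esr1 rose most clearly, together with Pebp1 and the sulfotransferases Sult2a6 and Sult2a4, while the fetal liver gene Afp fell. Esr1, the estrogen receptor alpha gene (chromosome 10, 4611989 to 5005633), rose 13.7-fold from 34.3 ± 3.08 to 471 ± 2.46 CPM (log2 change 3.78 ± 0.16 SE, adjusted p = 8.24e-07). Pebp1, a Raf kinase inhibitor gene (chromosome 5, 117282651 to 117287564), rose from 118 ± 7.48 to 293 ± 50.7 CPM (log2 change 1.31 ± 0.13, adjusted p = 0.00207). Sult2a6 rose to 8.78, 16.6 and 19.7 CPM in the 3 libraries, with 1 read in all of AHR Flox (adjusted p = 0.00138), and Sult2a4 rose 29.4-fold to 21.6 ± 8.93 CPM (adjusted p = 0.0155). Assignment within the Sult2a family is uncertain, since its copies on chromosome 7 share sequence. Afp (chromosome 5, 90490714 to 90508907) fell 4.77-fold from 5.02 ± 0.237 to 1.05 ± 0.0938 CPM (adjusted p = 0.0168).

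Alb, the albumin gene next to Afp (90460870 to 90476602), was 13.3-fold lower in mean, at 6311 ± 800 CPM in AHR KO against 84032 ± 5430 in AHR Flox. All 3 AHR KO libraries lay below all 3 AHR Flox libraries, but Alb missed the threshold (log2 change −3.74 ± 0.66, adjusted p = 0.0629). Alb passed without ARNT KO replicate 3, at a change of −3.74 ± 0.19 (adjusted p = 3.61e-06), within a range of 6.27e-10 to 0.219 over all alternatives. The remaining named calls were smaller. Atp10d, a phospholipid flippase gene, rose 2.85-fold, Gpr64 (now Adgrg2) rose 2.16-fold and Brpf3 rose 1.48-fold, while Gas2 fell 1.79-fold and Klhl5 fell 1.44-fold (adjusted p from 0.0236 to 0.0341). Of the called genes, Pebp1, Afp, Atp10d and Klhl5 lie on chromosome 5, as Alb does. A330049N07Rik fell from 5.03 ± 1.88 to 0.0217 CPM (adjusted p = 0.0033), and is named outside the naming rule, after its values were seen. Gpr64 (1.43), Gas2 (−0.76) and A330049N07Rik (−8.37) were also called in ARNT Flox against AHR Flox, each in the direction of its change in AHR KO. For these genes a state of the AHR Flox group was not told apart from an effect of AHR loss.

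The list of known AHR targets did not pass in AHR KO: edgeR called 0 of its 14 tested members, with 2 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone, while DESeq2 called 1 and limma-voom 0. The list's camera adjusted p was 0.586 toward lower values, with a median log2 change of −0.07 and a mean of 0.06. Cyp1a2, the liver form of the Cyp1a oxygenases, was at 314 ± 33.3 CPM against 462 ± 59.1 CPM (log2 change −0.56 ± 0.33, adjusted p = 0.547), and without ARNT KO replicate 3 its adjusted p was 0.0446, within a range of 0.0446 to 0.763 over all alternatives. Cyp1a1 (log2 change 0.09, adjusted p = 0.976) and Tiparp (0.03, adjusted p = 0.947), named outside the naming rule after their values were seen, gave values close to 0.

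Of 32 lists, 8 passed in AHR KO with camera at its preset correlation, 4 higher and 4 lower, while 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) or with fry (2). The count was 7 without ARNT KO replicate 3 (4 higher, 3 lower), and 5 without AHR Flox replicate 3, AHR KO replicate 1 or AHR KO replicate 3. In each of the 8, edgeR and limma-voom called 0 members over all genes, DESeq2 called 0 to 2, and 0 to 10 members had an unadjusted p under 0.05. Lymphocyte markers rose as a set (23 members, median log2 change 0.63, adjusted p = 2.41e-05), and 5 members were higher adjusted over the list alone. Their mean log2 CPM was low, at −0.12 in AHR Flox, 0.43 in AHR KO, 0.62 in ARNT Flox and 0.48 in ARNT KO. A low state of AHR Flox was thus not told apart from an effect of AHR loss on this list. Fatty acid oxidation genes had 31 of 38 members higher, with a median of 0.22 (adjusted p = 0.00549) and 0 called adjusted over the list alone. Hepatocyte identity genes were higher at a median of 0.25 (adjusted p = 0.00971), with Alb the 1 member lower over the list alone, and the unfolded protein response genes at 0.24 (adjusted p = 0.0449), a rise that rested on AHR KO replicate 3: the list's median was 0.0478 without it, and the list then tested lower (adjusted p = 0.992). Lower lists were erythrocyte markers (4 members, median −0.86, adjusted p = 0.00416, 3 lower adjusted over the list alone), cholesterol synthesis (−0.18, adjusted p = 0.00754), extracellular matrix (−0.31, adjusted p = 0.0449) and stellate cell markers (−0.21, adjusted p = 0.0449), the last 3 with 0 called over the list alone. The cholesterol list was split within AHR KO, at a mean log2 CPM of 6.07, 7.08 and 6.12 in replicates 1, 2 and 3. In AHR Flox it was at 6.55, 6.60 and 6.90, so AHR KO replicate 2 lay above all AHR Flox libraries. Of the 8 lists, only the lymphocyte and erythrocyte markers passed without each library in turn. For the erythrocyte list the value was adjusted p = 0.864 with an estimated correlation, and for the other 7 lists it was adjusted p = 0.994 with an estimated correlation.

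In all, 11 of 13968 genes were called in AHR KO, 7 higher and 4 lower, beside 1664 genes at an unadjusted p under 0.05 where 698 would fall by chance, and TMM without the 50 most abundant genes gave 8 higher and 8 lower. The count moved by over 1.5 times without any 1 library other than ARNT Flox replicate 1. It was 24 without AHR Flox replicate 2, where most were lower (8 higher, 16 lower), and 18 without ARNT KO replicate 1. Without ARNT KO replicate 3 it was 136 (83 higher, 53 lower, all 11 among them). It was 5 to 7 without each of the remaining libraries that moved it. Esr1, Pebp1 and Sult2a6 kept their calls under all 22 alternatives, and Sult2a4, Afp, Atp10d, Gpr64, Brpf3, Gas2 and Klhl5 lost theirs under 5 to 11, each without AHR Flox replicate 1, among others.

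Loss of ARNT went with higher Esr1 and Pebp1 as well, with lower Arnt, Gpr64, Rad51l1 and Cyp2g1, and with higher Atp2b2. Esr1 rose 6.17-fold from 39.0 ± 3.23 to 241 ± 57.9 CPM (log2 change 2.63 ± 0.15 SE, adjusted p = 2.67e-05). Pebp1 rose from 93.0 ± 3.16 to 223 ± 25.3 CPM (log2 change 1.26 ± 0.13, adjusted p = 0.0046). Atp2b2, a plasma membrane calcium pump gene, rose 2.79-fold to 7.27 ± 0.776 CPM (adjusted p = 0.0382). Gpr64 fell 2.31-fold to 5.76 ± 0.812 CPM (adjusted p = 0.0354), Rad51l1 (now Rad51b), a recombination repair gene, fell 2.21-fold to 14.6 ± 2.94 CPM (adjusted p = 0.0382), and Cyp2g1 fell 3.47-fold to 4.14 ± 0.779 CPM (adjusted p = 0.0485). Gpr64 (1.43), Rad51l1 (1.11), Cyp2g1 (1.94) and Atp2b2 (−1.35) were also called in ARNT Flox against AHR Flox, each opposite to its change in ARNT KO. For these genes a state of the ARNT Flox group was not told apart from an effect of ARNT loss. Akap6 fell from 1.03 to 0.153 CPM (adjusted p = 0.0382) and is named outside the naming rule, after its values were seen. Alb was at 51926, 53685 and 5740 CPM in ARNT KO replicates 1, 2 and 3, against 76038 ± 10275 CPM in ARNT Flox (log2 change −1.03, adjusted p = 0.897).

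Targets of AHR and of the hypoxia-inducible factors, which both need ARNT, did not pass as lists in the 12 libraries. In the AHR target list edgeR called 0 of 14 members, and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (median log2 change 0.05, mean −0.02, adjusted p = 0.953 toward lower values). In the hypoxia-inducible factor list edgeR called 0 of 32, with 5 at an unadjusted p under 0.05, 1 lower adjusted over the list alone and 1 called by DESeq2 (median −0.02, adjusted p = 0.189). In the circadian list edgeR, DESeq2 and limma-voom called 0 of 21, with 1 at an unadjusted p under 0.05 (median 0.06, mean −0.01, adjusted p = 0.991). Cyp1a2 was at 291, 265 and 780 CPM in ARNT KO replicates 1, 2 and 3, against 786 ± 46.7 CPM in ARNT Flox (log2 change −0.82 ± 0.33, adjusted p = 0.769). Cyp1a2 passed without ARNT KO replicate 3, at a log2 change of −1.50 ± 0.13 (adjusted p = 0.000495, within a range of 0.000495 to 1.00 over all alternatives). All 3 lists passed in that fit, but not with an estimated correlation (adjusted p = 0.466 for each with an estimated correlation). The AHR targets were then lower (median −0.29, adjusted p = 0.0364), with Cyp1a2 and Nqo1 (−1.09, adjusted p = 0.0245) called lower. Nqo1 had 398, 528 and 419 counts in AHR Flox, 1057, 996 and 647 in ARNT Flox, and 480 and 415 in ARNT KO replicates 1 and 2. Its fall was thus not told apart from a raised level in ARNT Flox. Cyp1a2 had 12669, 15511 and 10247 counts in AHR Flox, between its counts in ARNT Flox and in ARNT KO replicates 1 and 2. Part of the fall in Cyp1a2 was thus not told apart from such a level either. The hypoxia-inducible factor targets were lower too (−0.11, adjusted p = 0.0379, 2 called lower), and the circadian list was higher (0.15, adjusted p = 0.0364).

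The lists that passed in ARNT KO were 5 of 32, 2 higher and 3 lower, and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05). That count rose to 23 without ARNT KO replicate 3 (10 higher, 13 lower), to 11 without ARNT KO replicate 1, and to 9 without ARNT KO replicate 2 or ARNT Flox replicate 2. In each of the 5, edgeR and limma-voom called 0 members over all genes, DESeq2 called 0 to 4, and 1 to 17 members had an unadjusted p under 0.05. Cell cycle genes were higher in 31 of 32 members (median log2 change 0.95, adjusted p = 4.39e-12), 7 of them adjusted over the list alone (adjusted p = 0.736 with an estimated correlation). ARNT KO replicate 3 carried most of this: it exceeded the mean of replicates 1 and 2 by a median of 1.62 log2 units over the list, and without it the list's median was 0.28 (adjusted p = 0.0152). The unfolded protein response list rose (median 0.32, adjusted p = 7.45e-07, 4 adjusted over the list alone, and adjusted p = 0.736 with an estimated correlation). Its mean log2 CPM was 5.68 in AHR Flox, 5.31 in ARNT Flox and 5.63 in ARNT KO. The rise was thus not told apart from a lowered level in ARNT Flox. Genes of pericentral hepatocytes fell as a set (21 members, median −0.25, adjusted p = 7.45e-07, 1 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). Interferon response genes had a median of −0.23 (28 members, adjusted p = 3.75e-07, 0 adjusted over the list alone), and acute phase genes −0.14 (adjusted p = 0.0451, 0 over the list alone), both at adjusted p = 0.883 with an estimated correlation. With fry, 1 list passed, the bHLH-PAS family that includes Arnt (adjusted p = 0.00973), and without ARNT KO replicate 3 there were 3 with fry, that family, NRF2 targets and interferon response.

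Interferon genes were split within ARNT KO. Irf7, an interferon regulatory factor gene, was at 45.6, 45.1 and 200 CPM in ARNT KO replicates 1, 2 and 3, against 109 ± 4.16 CPM in ARNT Flox. Without replicate 3, all 28 interferon members were lower, 19 of them called and 25 adjusted over the list alone (median log2 change −0.91, adjusted p = 6.59e-27; adjusted p = 0.0601 with an estimated correlation, 0.000613 with fry). In that fit 6 of 27 NRF2 targets were called lower and 14 over the list alone (median −0.41, adjusted p = 2.18e-08; adjusted p = 0.379 with an estimated correlation), among them Cbr3 at −3.33 and Srxn1, sulfiredoxin, at −1.14. Cbr3, a carbonyl reductase gene, was at 0.900, 0.890 and 162 CPM in the 3 ARNT KO libraries against 9.07 ± 1.24 CPM in ARNT Flox. Its direction thus turned with replicate 3 (log2 change 2.59, adjusted p = 0.862, in 12 libraries). The NRF2 list had a mean log2 CPM of 6.08 in AHR Flox, 6.85 in ARNT Flox, and 6.25 and 6.18 in ARNT KO replicates 1 and 2. Cbr3 had 29, 13 and 23 counts in AHR Flox, 284, 335 and 197 in ARNT Flox, and 29 and 28 in those 2 knockout libraries. A raised state of ARNT Flox was thus not told apart from an effect of ARNT loss on these genes.

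**Figure D3:**
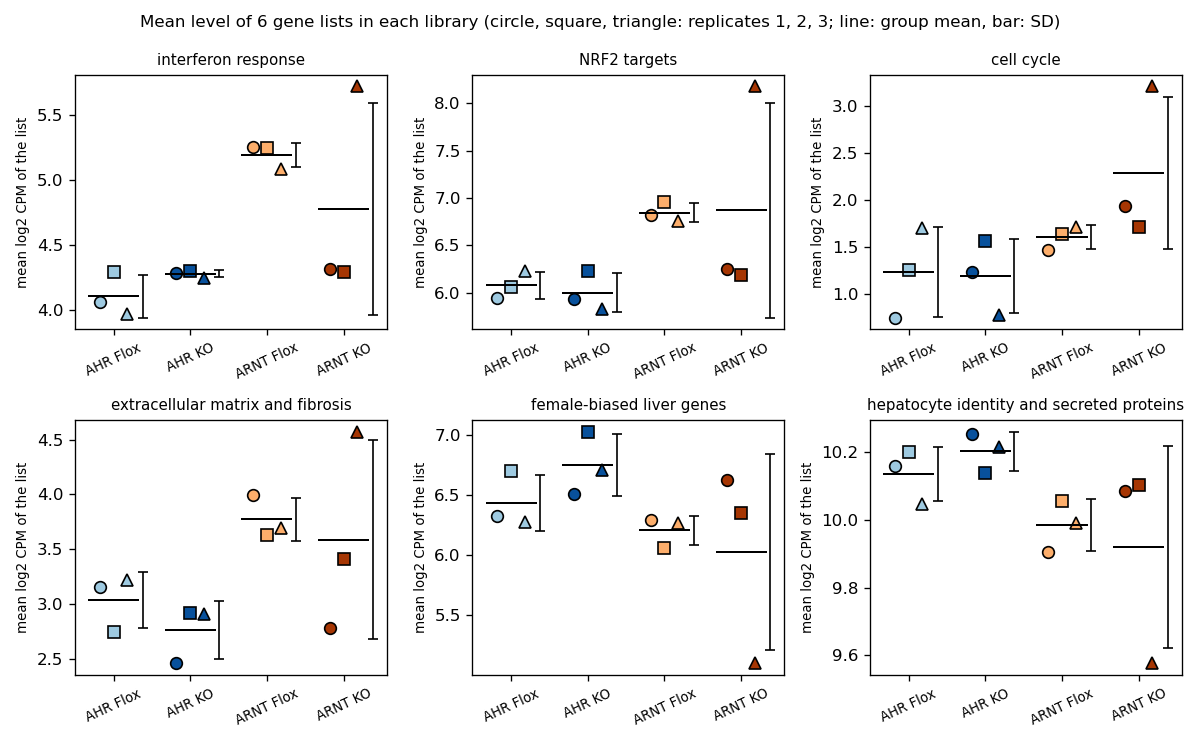
Mean log2 CPM over the members of 6 gene lists, one point per library, with a line at the mean and a bar for the SD of each group of 3. The interferon list is 1.09 higher in ARNT Flox than in AHR Flox, and 1.61 higher in ARNT KO replicate 3 than in AHR Flox.

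In all, 8 genes were called in ARNT KO, 3 higher and 5 lower, beside 822 at an unadjusted p under 0.05 where 698 would fall by chance. DESeq2 called 57, with more higher (32) than lower (25), and edgeR with only the groups of the contrast called 1. The main count of 8 moved by over 1.5 times without any 1 library other than AHR KO replicate 3. It was 13 without AHR KO replicate 1 and 193 without ARNT KO replicate 3 (52 higher, 141 lower, all 8 among them). It was 1 to 5 without each of the remaining libraries that moved it. Esr1 kept its call under all 22 alternatives, Pebp1 and Arnt lost theirs under 2, and Gpr64, Rad51l1, Atp2b2 and Cyp2g1 under 8 to 14.

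Both knockouts called 3 genes, Esr1 and Pebp1 higher in both and Gpr64 in opposite directions, where independent lists would share 0.0015 higher and 0.00336 opposite. There were 15 without ARNT KO replicate 3, of which 4 were higher in both, 2 lower in both and 9 opposite, where independent lists would share 0.307, 0.531 and 1.03. Those added included Cyp1a2 (−0.56 in AHR KO, −1.50 in ARNT KO) and Tuba8 (−1.26 and −3.32) lower in both, and the imprinted RNA H19 opposite (3.55 and −3.66). Tuba8 had 31, 33 and 35 counts in AHR Flox, 256, 251 and 185 in ARNT Flox, and 24 and 25 in ARNT KO replicates 1 and 2. Its fall in ARNT KO was thus not told apart from a raised level in ARNT Flox. Cyp1a2 was higher in ARNT Flox than in AHR Flox too, though ARNT KO replicates 1 and 2 lay below both Flox lines. H19 had 139, 291 and 239 counts in AHR KO, and 184 and 278 in ARNT KO replicates 1 and 2. It had 18, 15 and 17 counts in AHR Flox and 3027, 3848 and 1568 in ARNT Flox. Its opposite signs thus go with a difference between the control lines, and opposite calls need not be opposing effects of the deletions. ARNT KO replicate 3, left out of that fit, had 4169 counts of H19. A state of either control line was not told apart from an effect of a deletion on H19. Leaving out ARNT Flox replicate 2 left 1 gene called in both knockouts. The log2 changes of all tested genes correlated across genes at r = 0.05 and Spearman's rho = 0.00, and genes are not independent replicates. The recombinase line is not given in the sources used here. For Esr1 and Pebp1, an effect of a construct carried by both knockouts was thus not told apart from effects of the deletions.

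The effects of the knockouts were then compared directly, ARNT minus AHR. Gpr64, an adhesion receptor gene, rose in AHR KO and fell in ARNT KO, a difference of −2.32 ± 0.23 log2 units (adjusted p = 0.00741). Atp2b2 went the other way, at −1.21 in AHR KO (adjusted p = 0.0623) and 1.48 in ARNT KO, a difference of 2.70 ± 0.30 (adjusted p = 0.0112). Socs2, a suppressor of cytokine signaling gene, differed by −2.52 ± 0.36 (adjusted p = 0.0461), Rad51l1 by −1.75 ± 0.23 and Gas2 by 1.29 ± 0.17 (adjusted p = 0.0301 for both). Arnt itself differed by −1.30. Gpr64, Atp2b2, Rad51l1 and Gas2 also differed between the Flox lines, Gpr64 at 4.95 ± 0.844 CPM in AHR Flox and 13.3 ± 1.86 CPM in ARNT Flox against 10.7 ± 1.26 CPM in AHR KO and 5.76 ± 0.812 CPM in ARNT KO. The effect on Esr1 did not differ past the threshold (−1.15, adjusted p = 0.127), though without ARNT KO replicate 3 it did (−1.36, adjusted p = 0.00106), and Pebp1 differed by −0.05 (adjusted p = 0.969).

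Between the knockouts 10 lists differed, 4 higher and 6 lower in ARNT, and 0 with an estimated correlation (1 at an unadjusted p under 0.05; lowest adjusted p = 0.787 with an estimated correlation). Cell cycle genes differed by a median of 1.00 (adjusted p = 6.51e-06, 2 adjusted over the list alone) and lymphocyte markers by −0.60 (adjusted p = 1.10e-05, 6 over the list alone). Leaving out ARNT KO replicate 3 also gave 10 lists, 7 of them shared, with 1 by fry, interferon response, and a lowest adjusted p of 0.0946 with an estimated correlation. In all, 6 genes were called, 2 higher and 4 lower, beside 1328 at an unadjusted p under 0.05. The count was 194 without ARNT KO replicate 3 (53 higher, 141 lower, all 6 among them), 3 without AHR Flox replicate 1, AHR Flox replicate 3 or ARNT Flox replicate 2, 2 without ARNT KO replicate 2, and 1 without AHR KO replicate 2 or ARNT Flox replicate 3. Gpr64 kept its call under all 21 alternatives, Atp2b2 lost it under 2, and Arnt, Rad51l1, Gas2 and Socs2 under 8 or 9.

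More genes were called between the control lines (46) than in AHR KO (11) or ARNT KO (8), though without AHR Flox replicate 2 the Flox lines and AHR KO both had 24. In ARNT Flox against AHR Flox, interferon response genes were higher and unfolded protein response genes lower as lists at the preset correlation, while neither passed with an estimated correlation (adjusted p = 0.601 for both with an estimated correlation). Cd1d2, which encodes a lipid antigen presenting molecule (chromosome 3, 86986586 to 86989533), rose 69.4-fold from 0.322 ± 0.0819 to 22.9 ± 0.377 CPM (log2 difference 6.12 ± 0.22 SE, adjusted p = 1.29e-07). Rps3a, a ribosomal protein gene on the same chromosome with many processed copies, fell from 207 ± 24.7 to 76.8 ± 2.62 CPM (log2 difference −1.43 ± 0.10, adjusted p = 7.68e-05). H19 was 92.1 ± 27.4 CPM in ARNT Flox and 0.610 ± 0.0957 CPM in AHR Flox (log2 difference 7.24 ± 1.22, adjusted p = 0.0388). The other named differences were Col4a3 (2.91), Slc39a5 (2.29) and Cyp2g1 (1.94) higher, and H2-T10 (−2.07), Sdf2l1 (−1.94), Fgfbp3 (−1.49) and Wnt5b (−1.45) lower in ARNT Flox (adjusted p from 0.0156 to 0.0307). H2-Ea-ps, named after its values were seen, had 0 counts in ARNT Flox and was at least 9.47-fold lower there, against a floor of 3 counts per library. Reads of H2 and Gbp genes can be shared among similar copies.

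Of 32 lists, 14 differed between the Flox lines, 9 higher and 5 lower in ARNT Flox, and 0 passed with an estimated correlation (1 at an unadjusted p under 0.05; lowest adjusted p = 0.601 with an estimated correlation) or with fry (7 at an unadjusted p under 0.05). Without ARNT KO replicate 3 the count was 15 (9 higher, 6 lower), and 5 with fry, among them interferon response, macrophage and lymphocyte markers, while the lowest value with an estimated correlation was adjusted p = 0.0864. Interferon genes were higher in 28 of 28 members (median log2 difference 1.10, adjusted p = 4.73e-14), with Gbp2, Gbp7 and Tap1 called (named after their values were seen, as are the list members below) and 22 adjusted over the list alone. Lymphocyte markers (0.68, adjusted p = 6.59e-09, 6 over the list alone) and macrophage markers (0.51, adjusted p = 1.43e-08, 16 over the list alone) were higher with them. The unfolded protein response list was lower (−0.35, adjusted p = 5.29e-05), with Atf5, Sdf2l1, Pdia6 and Calr called and 5 adjusted over the list alone. Calr, the calreticulin gene, was at 258 ± 10.2 CPM in ARNT Flox and 612 ± 86.1 CPM in AHR Flox (log2 difference −1.25 ± 0.19, adjusted p = 0.0273). These 4 lists all stood at adjusted p = 0.601 with an estimated correlation. Also higher were the lists of extracellular matrix (0.58, adjusted p = 1.19e-06), sinusoidal endothelial (0.29, adjusted p = 1.99e-05), stellate cell (0.30, adjusted p = 0.000581) and neutrophil markers (1.00, adjusted p = 0.00368), NRF2 targets (0.42, adjusted p = 0.00368) and acute phase genes (0.36, adjusted p = 0.0244). Also lower were glucose and glycogen metabolism (−0.18, adjusted p = 0.00368), tryptophan metabolism (−0.26, adjusted p = 0.0066), hepatocyte identity (−0.18, adjusted p = 0.00849) and male-biased genes (−0.37, adjusted p = 0.00901). These 10 lists stood at adjusted p = 0.601 to 0.728 with an estimated correlation. In each of the 10, edgeR and limma-voom called 0 members over all genes, DESeq2 called 0 to 4, and 3 to 13 had an unadjusted p under 0.05.

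In all, 46 of 13968 genes were called between the Flox lines, 19 higher and 27 lower in ARNT Flox, beside 2774 at an unadjusted p under 0.05, and 23 with the replicate number as a block, 22 of them shared. Without ARNT KO replicate 3, which enters this contrast only through the shared error, the count was 1532 (898 higher, 634 lower, all 46 among them), without ARNT KO replicate 1 it was 85, and it was 12 to 24 without AHR KO replicate 2 or any 1 of the 6 Flox libraries. Cd1d2 and Rps3a kept their calls under all 22 alternatives, and H19, Col4a3, Slc39a5, Cyp2g1, H2-T10, Sdf2l1, Fgfbp3 and Wnt5b lost theirs under 4 to 11. Of the 45 called genes with a position, 7 lay within 20 Mb of Ahr or Arnt, 15.6% against 3.18% of the tested genes with a position (odds ratio 5.68), among them Acp1, Sntg2 and Tmem18 near Ahr (named after their values were seen) and Cd1d2 and Rps3a near Arnt. The enrichment was smaller without ARNT KO replicate 3, at 66 of 1519 calls or 4.34% (odds ratio 1.45, adjusted p = 0.0459).

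**Figure D4:**
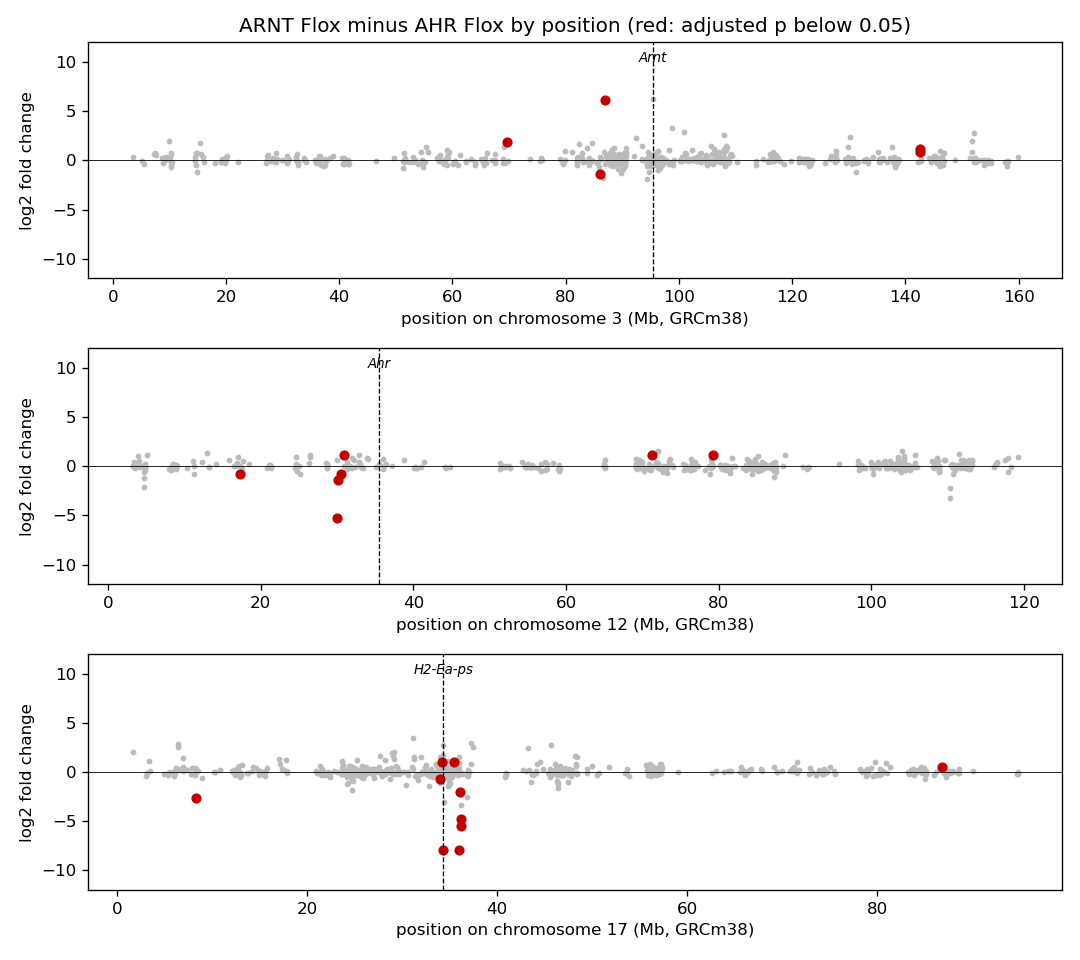
Log2 difference between ARNT Flox and AHR Flox against position on chromosomes 3, 12 and 17, one point per tested gene, with called genes marked. Cd1d2, at 6.12, lies near Arnt on chromosome 3, and Acp1, at 1.12, near Ahr on chromosome 12.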

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

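The contrast of the effects was planned; the counts over other splits of the samples were written after the results had been seen.

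The results below are those in which the effect of ARNT loss differed from that of AHR loss by the test of the difference itself, given as ARNT minus AHR in log2 units. Gpr64, an adhesion receptor gene, differed by −2.32 (adjusted p = 0.00741; 1.11 in AHR KO and −1.21 in ARNT KO). Atp2b2, a calcium pump gene, differed by 2.70 (adjusted p = 0.0112; −1.21 and 1.48). Rad51l1 differed by −1.75, Arnt by −1.30 and Gas2 by 1.29 (adjusted p = 0.0301 for each), and Socs2 by −2.52 (adjusted p = 0.0461). Of 100 splits of the libraries within both lines at once, the real one included, the real split gave 6 calls for the difference against at most 3 in the others, and 3 genes called in both knockouts against at most 1. Such splits also break up the effect of each knockout, so they bear on whether there is any effect at all, and not on a difference between the effects or an overlap beyond chance.

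Among gene lists the difference passed for 10, and 0 of these kept it with an estimated correlation (adjusted p = 0.787 with an estimated correlation for each). The medians were 1.00 for cell cycle (adjusted p = 6.51e-06), 0.93 for erythrocyte markers (adjusted p = 0.00565), 0.37 for fatty acid synthesis (adjusted p = 0.0202) and 0.33 for cholesterol synthesis (adjusted p = 0.000949). They were −0.60 for lymphocyte markers (adjusted p = 1.10e-05), −0.41 for interferon response (adjusted p = 9.93e-06), −0.28 for pericentral genes (adjusted p = 0.00287), −0.26 for acute phase (adjusted p = 0.0373), and −0.18 for both fatty acid oxidation (adjusted p = 0.00169) and hepatocyte identity (adjusted p = 0.0443). The fatty acid and cholesterol synthesis lists were split within AHR KO. AHR KO replicate 2 had a mean log2 CPM of 8.13 and 7.08 in these lists. It lay above all AHR Flox libraries, whose highest values were 7.94 and 6.90. AHR KO replicates 1 and 3 lay below all AHR Flox libraries in both lists. The AHR KO libraries thus did not share 1 direction for these 2 lists. Without ARNT KO replicate 3, 7 of the 10 kept the call, with a cell cycle median of 0.45 and an interferon median of −1.08. Lost were pericentral genes (−0.30, adjusted p = 0.107), fatty acid oxidation (0.00, adjusted p = 0.596) and hepatocyte identity, whose median was −0.0380 and which then tested higher (adjusted p = 0.745). The lists did not pass with an estimated correlation in that fit either (lowest adjusted p = 0.0946 with an estimated correlation, for interferon response).

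For the other counts the splits of 6 libraries are 10, too few for a share under 0.05. The real split, 1 of the 10 each time, called 11 genes against at most 2 for AHR, 8 against at most 1 for ARNT, and 46 against at most 0 for the Flox lines (edgeR; 2774 genes had an unadjusted p under 0.05 in the real split).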

How the results depend on the processing

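Limma-voom with sample quality weights was added after the data were seen; the other alternatives were planned. Esr1 in both knockouts, Pebp1 and Sult2a6 in AHR KO, Cd1d2 and Rps3a between the Flox lines and the difference in Gpr64 kept their call under every alternative run. Over all alternatives, the called genes that the naming rule named, in the contrast it named them for, kept direction and call in 520 results and lost the call with the same direction in 200; lists did so in 636 and 129. DESeq2 called 359 genes for AHR, 57 for ARNT, 148 for the difference, 566 for the Flox lines and 13 in both knockouts. With sample quality weights these were 82, 422, 238, 2395 and 12. No filter gave 28 calls for AHR (13 higher, 15 lower), and 1 CPM in 3 samples gave 19 (9 higher, 10 lower). Limma-voom gave 5 for ARNT. With only the groups of a contrast there was 1 call for ARNT, 1615 for the Flox lines and 1 in both. The replicate block gave 3 for ARNT and 23 for the Flox lines. With an estimated correlation 0 lists passed in any of the 4 contrasts, and with fry 0, except 1 for ARNT. Leaving out 1 library gave 5 to 136 calls for AHR, 1 to 193 for ARNT, 1 to 194 for the difference, 12 to 1532 for the Flox lines and 1 to 15 in both, each highest without ARNT KO replicate 3; lists ranged from 5 to 10, 5 to 23, 8 to 12 and 12 to 16. The interferon median for ARNT was 0.00 without ARNT KO replicate 1 or 2. Reversed results were the unfolded protein response list in AHR KO without AHR KO replicate 3 (median 0.0478, tested lower at adjusted p = 0.992, over a leave-one-out range of 0.0478 to 0.335) and hepatocyte identity in the difference without ARNT KO replicate 3 (−0.0380, tested higher at adjusted p = 0.745, range −0.281 to −0.0380). For ARNT, genes that were not called turned lower and passed without ARNT KO replicate 3, the lower end of these leave-one-out ranges: Abcc4 −1.25 to 0.94, Cbr3 −3.33 to 3.16, Gstm3 −2.46 to 1.71, Gstp1 −1.11 to 0.79, Nqo1 −1.09 to 0.88, Oas3 −1.25 to 0.45, Scd2 −1.66 to 1.14, Srxn1 −1.14 to 1.27 and Ubd −2.42 to 0.88. So did Abcc4 (−1.12), Cbr3 (−3.01), Gstm3 (−2.29), Oas3 (−1.07) and Ubd (−2.12) with quality weights. Except where a library or group was left out, the cause was not tested.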

Other observations

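ARNT KO replicate 3 differed from ARNT KO replicates 1 and 2 in many gene groups at once, given here as a description of 1 library. Relative to the mean of the other 2, its cholangiocyte markers were higher by a median of 1.99 log2 units, cell cycle genes by 1.62 (30 of 32 members), interferon genes by 1.59, NRF2 targets by 1.58, extracellular matrix genes by 1.55 and macrophage markers by 0.83, each above all of 10000 random lists matched in size and level. The glutathione transferase gene Gstm3 was at 1278 CPM against 36.2 and 37.1 CPM, the carbonyl reductase gene Cbr3 at 162 CPM against 0.900 and 0.890 CPM, and Cdkn1a, a cell cycle inhibitor gene, at 95.4 CPM against 6.95 and 9.15 CPM. Female-biased liver genes were lower by 1.56 log2 units in that library, with Sult3a1 at 0.861 CPM against 19.9 and 9.91 CPM.

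Without ARNT KO replicate 3, female-biased genes were higher in ARNT KO (median 0.22, adjusted p = 0.0379; adjusted p = 0.536 with an estimated correlation), with Cyp2b13 (1.91) and Sult3a1 (3.98) called. Male-biased genes did not pass as a list there (0.11, adjusted p = 0.378), though of them Cyp2d9 was called higher (3.56, adjusted p = 0.00224) and Gstp1 lower (−1.11). Genes of glucose and glycogen metabolism were higher as well (0.20, adjusted p = 0.0022; adjusted p = 0.466 with an estimated correlation), with Pygl and Dak called. Of the hypoxia-inducible factor targets, Ndrg1 (−0.71) and Hk2 (−0.92) were called lower in that fit. The counts of Cyp2b13, Sult3a1, Gstp1, Pygl, Dak, Ndrg1 and Hk2 did not overlap between the 2 Flox lines. Sult3a1 had 842, 629 and 1099 counts in AHR Flox, 49, 8 and 27 in ARNT Flox, and 641 and 312 in ARNT KO replicates 1 and 2. The glucose list had a mean log2 CPM of 7.71 in AHR Flox, 7.52 in ARNT Flox, and 7.79 and 7.81 in those 2 knockout libraries. For these genes and that list a state of ARNT Flox was not told apart from an effect of ARNT loss. Cyp2d9 counts in ARNT KO replicates 1 and 2 lay above those of both Flox lines.

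All tests of explanations below were chosen after the results had been seen.

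Esr1 counts were higher in every knockout library, at 199 to 473 CPM against 30.9 to 42.4 CPM in the Flox libraries, and Alb was lowest in the AHR KO libraries and ARNT KO replicate 3 (0.547% to 0.684% of counts) and less low in ARNT KO replicates 1 and 2 (5.10% and 5.39%, against 7.14% to 8.76% in ARNT Flox). Fewer hepatocytes in AHR KO are argued against, since the other 27 hepatocyte genes had a median log2 change of 0.254 there (quartiles 0.09 and 0.35), while Alb was at −3.74. An exchange of ARNT KO replicate 3 with an AHR KO library is argued against too: on 15 genes that part the lines, with AHR Flox at 0 and ARNT Flox at 1, its median position was 1.00 (quartiles 0.958 and 1.09). A candidate explanation that stays open is a construct with estrogen receptor sequence inserted at the Alb locus as part of an inducible recombinase. The recombinase line is not given in the sources used here. Pebp1, called in both knockouts, lies on chromosome 5 as Alb does, but outside the 20 Mb window of the next test. Without ARNT KO replicate 3, calls in AHR KO lay within 20 Mb of Alb more often than tested genes, which such an insertion may bring with its donor chromosome. The counts were 10 of 133 against 187 of 13873 (odds ratio 6.23, Fisher's exact test, two-sided p = 1.25e-05, adjusted p = 0.00014 over 40 tests). Calls in ARNT KO in that fit gave 9 of 191 (odds ratio 3.75, adjusted p = 0.0076). All of those 9 but Cox18 were also called between the Flox lines in that window and fit. That contrast holds no knockout group, so the ARNT KO excess may come from the control lines rather than such an insertion. Of the 10 in AHR KO, Ociad2 and Sowahb were also called between the Flox lines. With 12 libraries the counts were 2 of 11 in AHR KO and 0 of 7 in ARNT KO.

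Interferon response genes were lower in ARNT KO than in ARNT Flox once ARNT KO replicate 3 was left out. The mean change was −0.892 log2 units for the 28 interferon genes and −0.407 for 50 macrophage and lymphocyte markers, which thus fell too. The gap of −0.485 argues against an even loss of immune cells as the whole cause (permutation test over genes, 100000 permutations, p = 2e-05). Genes are not independent, and the test permutes genes rather than mice. It does not cover a loss limited to the immune cells that carry the interferon genes. A raised interferon state in the ARNT Flox mice, from health or housing, remains a candidate explanation: the list stood 1.09 log2 units above AHR Flox in ARNT Flox, and 0.197 above it in ARNT KO replicates 1 and 2, against an SD of 0.165 among AHR Flox libraries. An effect of ARNT loss itself stays open as well and was not tested apart from that state, since ARNT Flox is the only control group of the line. ARNT KO replicate 3 stood 1.61 above AHR Flox.

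Genes called between the Flox lines lay near the targeted genes more often than other tested genes (7 of 45 calls within 20 Mb of Ahr or Arnt; odds ratio 5.68, Fisher's exact test, two-sided p = 0.000499, adjusted p = 0.00399 over 40 tests), but the odds ratio was 1.45 without ARNT KO replicate 3 (66 of 1519 calls, adjusted p = 0.0459). The Ahr window held 5 of them (odds ratio 18.8; 1.51 without that library, adjusted p = 0.330) and the Arnt window 2 (odds ratio 1.83, Fisher's exact p = 0.309). A physiological state of the ARNT Flox mice alone is argued against for 6 of these genes, but not for Pdia6, a protein folding gene with a ratio of 0.313. The difference of the 7 between the knockout groups was 0.946 times that between the Flox groups in the median (quartiles 0.883 and 1.22). It was 0.353 for the other 39 called genes (quartiles 0.129 and 0.639). These 39 include 8 calls in the H2 region of chromosome 17, with ratios from 0.613 (Tap1) to 1.499 (H2-T10). Dact1 (1.11) and B3galnt1 (1.192), outside both windows, also kept their difference. Persistence between the knockout groups was thus not limited to the Ahr and Arnt windows. A state shared by the Flox and knockout mice of a line would persist in the same way, so these ratios do not bear on it. Donor sequence kept around the floxed alleles may explain the 6 genes other than Pdia6, and it was not tested on sequence. The H2 region of chromosome 17, chosen after its calls were seen, held 8 calls (odds ratio 21.6; 38 calls and 2.94 without ARNT KO replicate 3), so the lines could also differ there. All 8 kept their direction between the knockout groups, at the ratios given above.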
